A study of Sus scrofa with 2 samples.

How the data were processed

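Longissimus dorsi, the long muscle of the back, was taken from crossbred barrows (castrated male pigs) of Duroc boars and Yorkshire-Landrace sows, per the labels. The study used 16 pigs of 79.0 ± 1.5 kg from 8 litters, with 8 pigs in each arm. The control arm was kept at 22 °C and the heat arm at 30 °C for 21 days. There was 1 messenger RNA library per arm. Whether the RNA of several pigs was pooled into a library is not given in the sources used here. Per the labels' protocols, each library was made from 3 µg of total RNA by poly(A) selection, random priming and 10 cycles of PCR, with fragments of about 200 bp. The kit as labelled is not described as marking strand, so reads of overlapping or antisense genes cannot be told apart.

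The deposited table gives 1 RPKM value (reads scaled to gene length and to the library total) per gene and library, as the authors computed it. Bowtie, TopHat 1.4.0, Cufflinks 1.3.0 and the Sscrofa10.2 build are named, with no role or order, per the submitters' processing notes. Which tool counted the reads, how reads with several matches were treated and where gene lengths came from is not given in the sources used here. Near-identical genes and pseudogenes could share reads, so single genes of such families (HSP90AA1 and HSP90AB1, GAPDH, FTL, TPI1, ribosomal proteins) are uncertain. The table had 27987 entries, of which 22740 carried an Ensembl pig gene identifier and 5247 carried a running name with no gene identifier, which the table does not explain. A table of pig gene names matched 11374 entries to a symbol. No genome of the authors' build was used here, so no coordinates are given. In all, 6589 entries were at 0 in both libraries, 1030 were above 0 in the control library only and 818 in the heat library only.

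Depth was recovered from the values. For a gene, the ratio of its RPKM values is a ratio of whole reads times 1 fixed factor, the ratio of the library totals. The factor most frequent among low genes was 1.03 (control over heat). With it, 99.9% of 13134 entries with a mean RPKM under 5 and a value above 0 in both libraries gave a pair of whole reads of at most 1000. With a wrong factor 2.76% did. The smallest such pair is a minimum, since the true pair can be a multiple. Library totals were then chosen so that gene lengths came out whole within 0.01 bp, which held for 57.1% of 1604 genes scanned, where 60.8% of pairs of whole numbers have no common factor. Gene lengths recovered this way rest on the minimum reads, so for genes with many reads they can be far below the true length. The estimated totals were 23608242 reads for the control library and 22863584 for the heat library. A single read on a gene of 1 kb was thus worth 0.0424 RPKM in the control library. Clopper-Pearson 95% intervals of the RPKM ratio were computed from the minimum reads, so they are wide rather than narrow. PCR reads without molecular identifiers are not independent molecules, and the intervals cover counting error only.

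The effect was log2((heat RPKM + 1)/(control RPKM + 1)), over genes with a mean RPKM of at least 1. A pseudocount of 1 understates the difference of low genes. With 1 library per group no significance test can be made across pigs, so genes were counted by size, at a log2 ratio of at least 1 in size (2-fold). The genes named were chosen by a fixed rule. Among genes with a symbol and a mean RPKM of at least 5, it takes up to 15 per direction past 2-fold. It also takes the 2 highest and the 2 lowest members of each gene list and the 10 genes with the highest mean RPKM. A symbol on several entries was taken from the highest. The rule, the 36 gene lists, the design and most alternatives were fixed before the data were examined. Members were matched by exact symbol or a listed alternative symbol. A wider match on reference synonyms, tried first, tied 2 members to wrong genes and was dropped after list values had been seen. Of 949 listed members 634 were matched, and the other 315 are not analysed here. HSPA1A, HSPB1, CRYAB and the myosin heavy chains MYH1, MYH2, MYH4 and MYH7 are among these.

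For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5. Chance would give about 1.7 such lists among the 34 tested if genes varied independently of each other. Genes of a list can vary together and some lists share members, so more lists could stand apart between any 2 libraries. The percentile describes these libraries and is no test of temperature.

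The steps were tested on simulated reads, drawn from the mean expression of the real genes. Independent gene to gene noise with an assumed SD of 0.2 (log2) was added. The simulated totals were somewhat lower than the estimated ones, with the heat library the larger, and gene lengths were drawn at random. Over all entries with simulated reads in both libraries, 100% of the minimum reads were at or below the true reads. Of these, 77.0% were equal to them, and 97.1% of the intervals held the true ratio. Among 13159 genes with a simulated mean RPKM of at least 1, the size rule called 100% of those made 4-fold higher and 80% of those made 4-fold lower. It called 0% of those made 1.5-fold higher or lower and 0.177% of unchanged genes, a share that depends on the assumed SD. Lists of 20 genes stood apart in 3% of 200 unshifted lists and in 96% of 50 lists shifted by 0.2. Unshifted lists were drawn at random from the same independent genes as the random lists, so a low share was set by this design. It gives no error rate for lists whose genes vary together.

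Alternatives were other pseudocounts (0.1 and 5), other filters (none, or a mean RPKM of at least 5), centring on the median, rescaling by a trimmed mean (30% of ratios and 5% of means trimmed at each end), rescaling without the 10 highest genes, and summing entries of a symbol. A threshold per expression bin (over 3 scaled median absolute deviations), the list mean, and random lists without matching were also planned. Alternatives added after seeing the data were matching on recovered gene length, matching on 5 expression bins with 4 length bins in each, drawing from the 100 genes nearest in expression, use of genes with a symbol only, and a counting interval that excludes 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.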

Results

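Messenger RNA of longissimus dorsi muscle was measured in 2 libraries, 1 from pigs kept at 22 °C and 1 from pigs kept at 30 °C for 21 days. The control library held an estimated 23608242 reads and the heat library 22863584, as recovered from the deposited RPKM values. Of 13191 genes with a mean RPKM of at least 1, 6990 had a symbol. The 10 genes with the highest mean RPKM took 36.1% of summed RPKM in the control library and 36.5% in the heat library. They were led by ACTA1, skeletal muscle actin, at 68749 and 65219 RPKM, and included the glycolytic enzymes GAPDH and ENO3, the fast fibre genes MYL11, TNNC2, MYL1 and TPM1, and the mitochondrial genes ATP6 and COX3.

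The comparison asked how the muscle transcriptome differed after constant heat. The fuel regulators PDK4 and PFKFB3 and the glucocorticoid-induced FKBP5 were higher in the 30 °C library, and the fatty acid genes SCD and FASN were lower. PDK4 (ENSSSCG00000015334), a kinase that shuts down pyruvate dehydrogenase, stood at 33.8 RPKM in the control library and 86.1 in the heat library, a ratio of 2.54 with a 95% counting interval of 2.39 to 2.71. FKBP5 (ENSSSCG00000001549), a glucocorticoid receptor co-chaperone, went from 9.33 to 21.2 RPKM, a ratio of 2.27 (2.00 to 2.58). PFKFB3 (ENSSSCG00000011133), which makes the activator of phosphofructokinase, went from 4.56 to 10.21 RPKM (log2 ratio 1.01). SPP1 (ENSSSCG00000009216), the secreted glycoprotein osteopontin, had the highest log2 ratio among these genes, 1.45, from 5.57 to 16.9 RPKM. ART3 (ENSSSCG00000008976), a membrane-anchored protein of the ADP-ribosyltransferase family, stood at 22.4 and 49.1 RPKM (log2 ratio 1.10).

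In the other direction, SCD (ENSSSCG00000010554), the desaturase that makes oleic acid, stood at 34.5 RPKM in the control library and 10.7 in the heat library, a ratio of 0.309 (0.280 to 0.340). FASN (ENSSSCG00000029944), fatty acid synthase, went from 16.0 to 6.998 RPKM, a ratio of 0.438 (0.400 to 0.479). PVALB (ENSSSCG00000000138), the calcium buffer parvalbumin of fast fibres, went from 226 to 93.7 RPKM, a ratio of 0.415 (0.388 to 0.443). The small nucleolar RNA SNORD99 was at 6.30 and 16.0 RPKM, which rests on at least 11 and 27 reads. With a pseudocount of 5 the log2 ratios of FASN (-0.81), ART3 (0.98), SNORD99 (0.89), FKBP5 (0.87) and PFKFB3 (0.67) were under 1 in size, and with centring on the median that of PFKFB3 was 0.96.

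**Figure D1:**
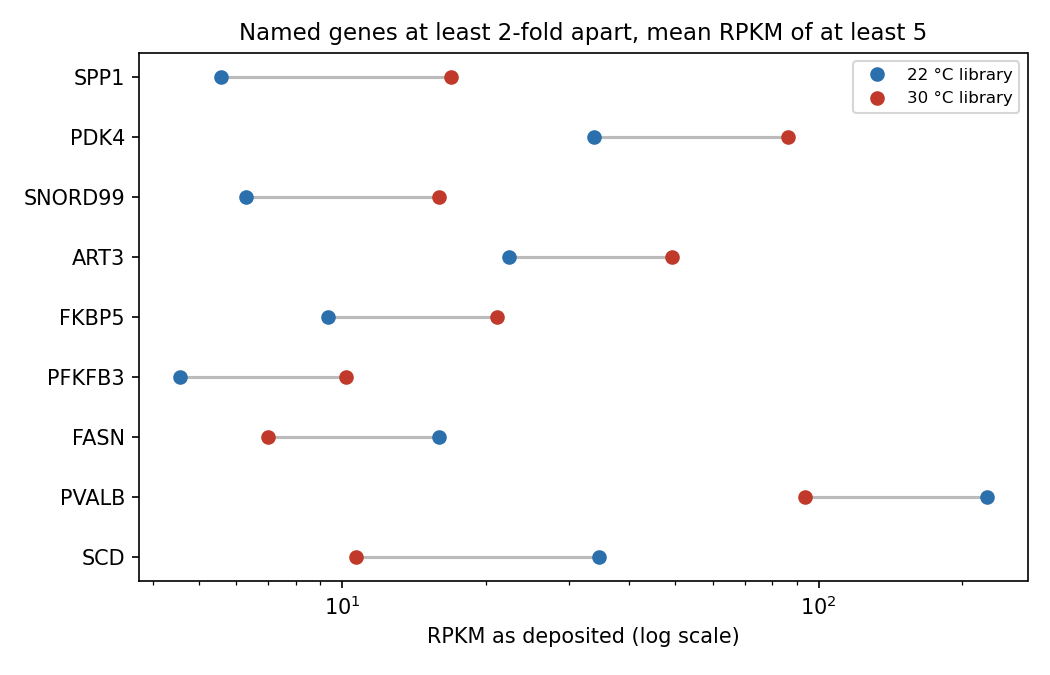
RPKM as deposited (log axis) of the 9 genes with a symbol, a mean RPKM of at least 5 and a log2 ratio of at least 1 in size. Each line joins the 22 °C library (blue) and the 30 °C library (red) of a gene, and SCD, PVALB and FASN are the 3 that were lower at 30 °C. There is 1 library per group, so no error between pigs can be drawn.

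In all, 83 genes were at least 2-fold higher and 77 at least 2-fold lower in the heat library on the log2(RPKM + 1) scale, 1.21% of those compared. The balance turned with the scaling, with 68 higher and 86 lower after centring on the median, 68 and 83 after trimmed mean rescaling, and 97 and 72 when rescaled without the 10 highest genes. Only 10 of the higher and 10 of the lower genes had a symbol, and 8 of these 20 were small nucleolar RNAs. The 4 others had a mean RPKM under 5. LYZ, the lysozyme of macrophages, is named from the macrophage list, while the other 3 were singled out after their values were seen. LYZ went from 1.09 to 3.29 RPKM (log2 ratio 1.04). TFPI, an inhibitor of blood coagulation, went from 1.03 to 3.16 RPKM (1.03). TRARG1, a protein of insulin-dependent glucose transporter vesicles, stood at 2.21 and 0.415 RPKM (-1.18), and VMO1 at 4.02 and 1.13 RPKM (-1.24) on at least 11 and 3 reads, with a counting interval of the RPKM ratio that holds 1 (0.050 to 1.07). With centring on the median the log2 ratios of LYZ (0.99) and TFPI (0.98) were under 1, and with a pseudocount of 5 all 4 were, from -0.56 for VMO1 to 0.45 for LYZ. The median log2 ratio of all genes was 0.05, with 95% of genes between -0.57 and 0.66. Across genes the libraries had a Pearson r of 0.984 and a Spearman rho of 0.963 (genes are not independent replicates). No difference here has a replicate check, and temperature, pigs, handling and library cannot be told apart. Counts depended on the pseudocount, with 290 higher and 193 lower at 0.1, and 7 and 20 at 5.

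**Figure D2:**
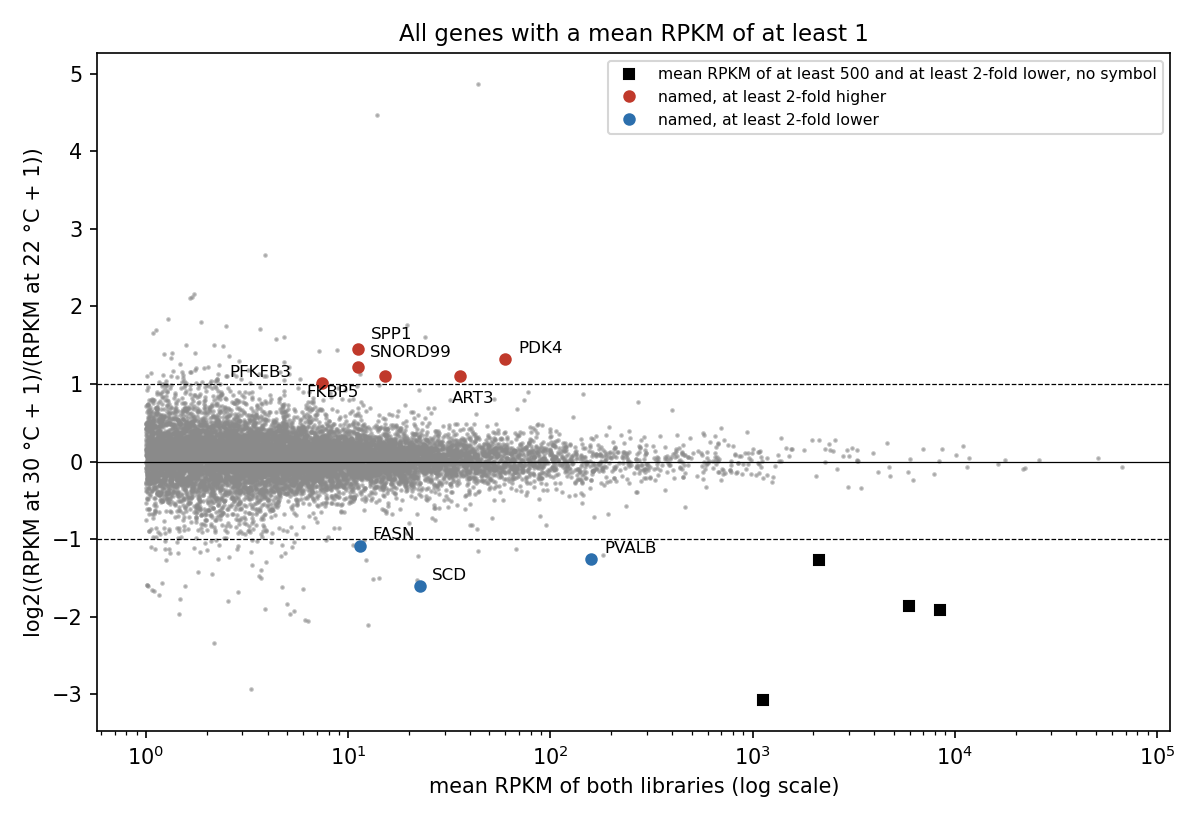
Log2 ratio of the 30 °C to the 22 °C library (vertical axis) against the mean RPKM of both libraries (horizontal log axis) for the 13191 genes with a mean RPKM of at least 1. Dashed lines mark 2-fold, coloured points the named genes past it with a mean RPKM of at least 5, and black squares the 4 genes without a symbol that had a mean RPKM of at least 500 and were at least 2-fold lower.

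Genes listed as glucocorticoid responsive, which include the receptor gene NR3C1, were higher as a group. Only 12 of 19 listed members were matched. Of 12 measured members, 9 had a log2 ratio above 0 and 3 were at least 1.5-fold higher, with a group median of 0.16 at percentile 98.7 among random lists of like expression. PDK4 (1.32) and FKBP5 (1.10) were the 2 highest members, while PER1 (88.3 and 83.7 RPKM) and ZBTB16 (16.5 and 15.9) were the lowest. Genes of muscle proteolysis and autophagy had a median of 0.14 (percentile 99.6), with 21 of 24 members above 0, and FBXO32, TRIM63 and FOXO1 are members of both lists. They were led by FBXO32, the muscle ubiquitin ligase atrogin-1, at 19.96 and 31.3 RPKM, and by FOXO3, a transcription factor of atrophy genes, at 10.5 and 14.1. ULK1, an autophagy kinase, was at 29.2 and 25.03 RPKM, and the mitochondrial ubiquitin ligase MUL1 at 14.1 and 13.4. Proteasome subunits had a median of 0.13 (percentile 99.1), with 17 of 22 above 0, from PSME1 (0.29) and PSMD14 (0.26) to PSMD3 (-0.09) and PSMD4 (-0.10). Against random lists drawn without regard to expression the percentiles were 92.5 for the glucocorticoid group, 95.7 for proteolysis and 91.7 for the proteasome, so none of the 3 then stood apart. The glucocorticoid group also stayed inside with a pseudocount of 5 (96.2), with matching on length (93.3) and, narrowly, with matching on expression and length (97.47), proteolysis (96.1) and the proteasome (91.1) with matching on length, and the proteasome by its mean (95.6).

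The heat shock protein group, which holds chaperones, their partners and the factors HSF1 and HSF2, had a median log2 ratio of 0.12 (percentile 99.3). Of 26 measured members, 20 were above 0 and none was at least 1.5-fold apart on the log2(RPKM + 1) scale. Only 28 of 40 listed members were matched, and HSPA1A, HSPB1 and CRYAB are among those missing. The cytosolic chaperones HSP90AB1 (75.8 to 105 RPKM, log2 ratio 0.47) and HSP90AA1 (212 to 280, 0.40) were the highest members. DNAJB1, a partner of HSP70 (34.3 to 26.4, -0.36), and the mitochondrial chaperone TRAP1 (16.8 to 13.7, -0.28) were the lowest. Endoplasmic reticulum stress genes had a median of 0.16 (percentile 98.0), with 11 of 16 above 0. Only 16 of 25 listed members were matched, without DDIT3, ATF4, HERPUD1 and TRIB3. HSPA5, a chaperone of that compartment singled out after its value was seen, was at 38.9 and 37.5 RPKM (-0.05). SEL1L, part of the degradation machinery of that compartment, had the highest ratio (0.39) and PDIA3, a disulfide isomerase, came next (0.37), while DNAJB11 was at -0.16 and CRELD2 at -0.16. Interferon and inflammatory genes had a median of 0.18 (percentile 98.4), with 16 of 20 above 0. OAS2, an antiviral enzyme, went from 4.51 to 7.89 RPKM and the cytokine IL18 from 1.31 to 2.56. USP18 (2.22 to 1.60) and the chemokine CCL5 (22.6 to 18.3) lay on the other side. Macrophage markers had a median of -0.08 and lymphocyte markers of 0.04, both within the random range. These 3 calls were lost under some alternatives. Without matching, the percentile was 91.6 for heat shock proteins and 95.1 for endoplasmic reticulum stress. With matching on length they were 91.1 and 94.95, and by list means 96.15 and 91.3. The heat shock call was also lost with no filter (96.45). The interferon group was inside the range by its mean (97.2), with a pseudocount of 5 (93.1) and with a mean RPKM of at least 5 (95.6).

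Genes of fatty acid and triglyceride synthesis were lower in the heat library, with a median of -0.14 (percentile 0.82) and 10 of 13 measured members below 0. SCD (-1.61) and FASN (-1.09) were the 2 lowest members. LPIN1, a phosphatidate phosphatase (11.9 to 18.0 RPKM, 0.56), and ME1, a source of NADPH (7.35 to 9.32, 0.30), were the highest members. Adipocyte markers had a median of -0.10 over 8 genes, within the random range. The lipid droplet genes CIDEC (7.56 to 3.48 RPKM) and PLIN1 (10.1 to 6.64) were the lowest of these, and PLIN4 (33.7 to 39.6) and ADIG (1.02 to 1.05) the highest. Among genes with a mean RPKM of at least 5 the synthesis group was at percentile 4.54 and no longer stood apart, while adipocyte markers then did (1.83). By their list mean adipocyte markers also stood apart on the low side (2.08).

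Glycolysis and glycogen genes had a median of -0.13 (percentile 0.06), with 18 of 27 members below 0. The glycolytic enzymes PKM (3834 to 3026 RPKM, -0.34) and TPI1 (3322 to 2645, -0.33) were the lowest. PFKFB3 (1.01) and GYG1, the primer of glycogen synthesis (0.17), were the highest. Nuclear genes of the respiratory chain had a median of -0.07 (percentile 0.59), with 29 of 37 below 0, from NDUFA2 (-0.36) and ATP5ME (-0.24) to NDUFA8 (0.17) and UQCRC2 (0.28). Respiratory chain genes of the mitochondrial genome had a median of 0.16 (percentile 99.7), from ND4L (1347 and 1350 RPKM) and ND3 (3276 and 3301) to ND2 (0.28) and ATP8 (0.30). All 13 were above 0 as deposited, and 9 lay above the median of all genes. Genes of the same small genome can vary together, so these are not independent results. Together these 13 genes took 8.32% of summed RPKM in the control library and 9.26% in the heat library. By list means the glycolysis group was at percentile 7.56 and the nuclear chain at 5.62, and the mitochondrial genes were at 93.4 without matching and 91.9 with matching on length, all inside the random range.

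Extracellular matrix genes were lower together, with a median log2 ratio of -0.20 (percentile 0 among 10000 random lists) and 35 of 41 measured members below 0. The counting interval of the RPKM ratio lay below 1 for 29 members and above 1 for 2. LOXL1, which cross-links elastin, went from 3.26 to 2.11 RPKM (-0.45) and fibromodulin, FMOD, a collagen-binding proteoglycan, from 12.8 to 9.18 (-0.43). The protease inhibitor TIMP1 (13.01 to 17.5, 0.40) and the proteoglycan BGN (54.9 to 62.4, 0.18) lay on the other side. Fibroblast markers also had a low median, -0.19 over 9 genes (percentile 0.41), and 3 of the 9 are matrix genes of the first list. They ran from PDGFRA (-0.33) and PCOLCE (-0.32) to FBLN1 (0.12) and DPP4 (0.31). The counting intervals of FBLN1 and DPP4 hold 1, but they rest on minimum reads (18 and 19 for FBLN1) and can be too wide. By the list mean the fibroblast group was at percentile 5.56. The matrix group stood apart under all 14 alternatives run on the lists, 4 of which shift all genes nearly alike or touch 1 symbol and so can hardly move a percentile.

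**Figure D3:**
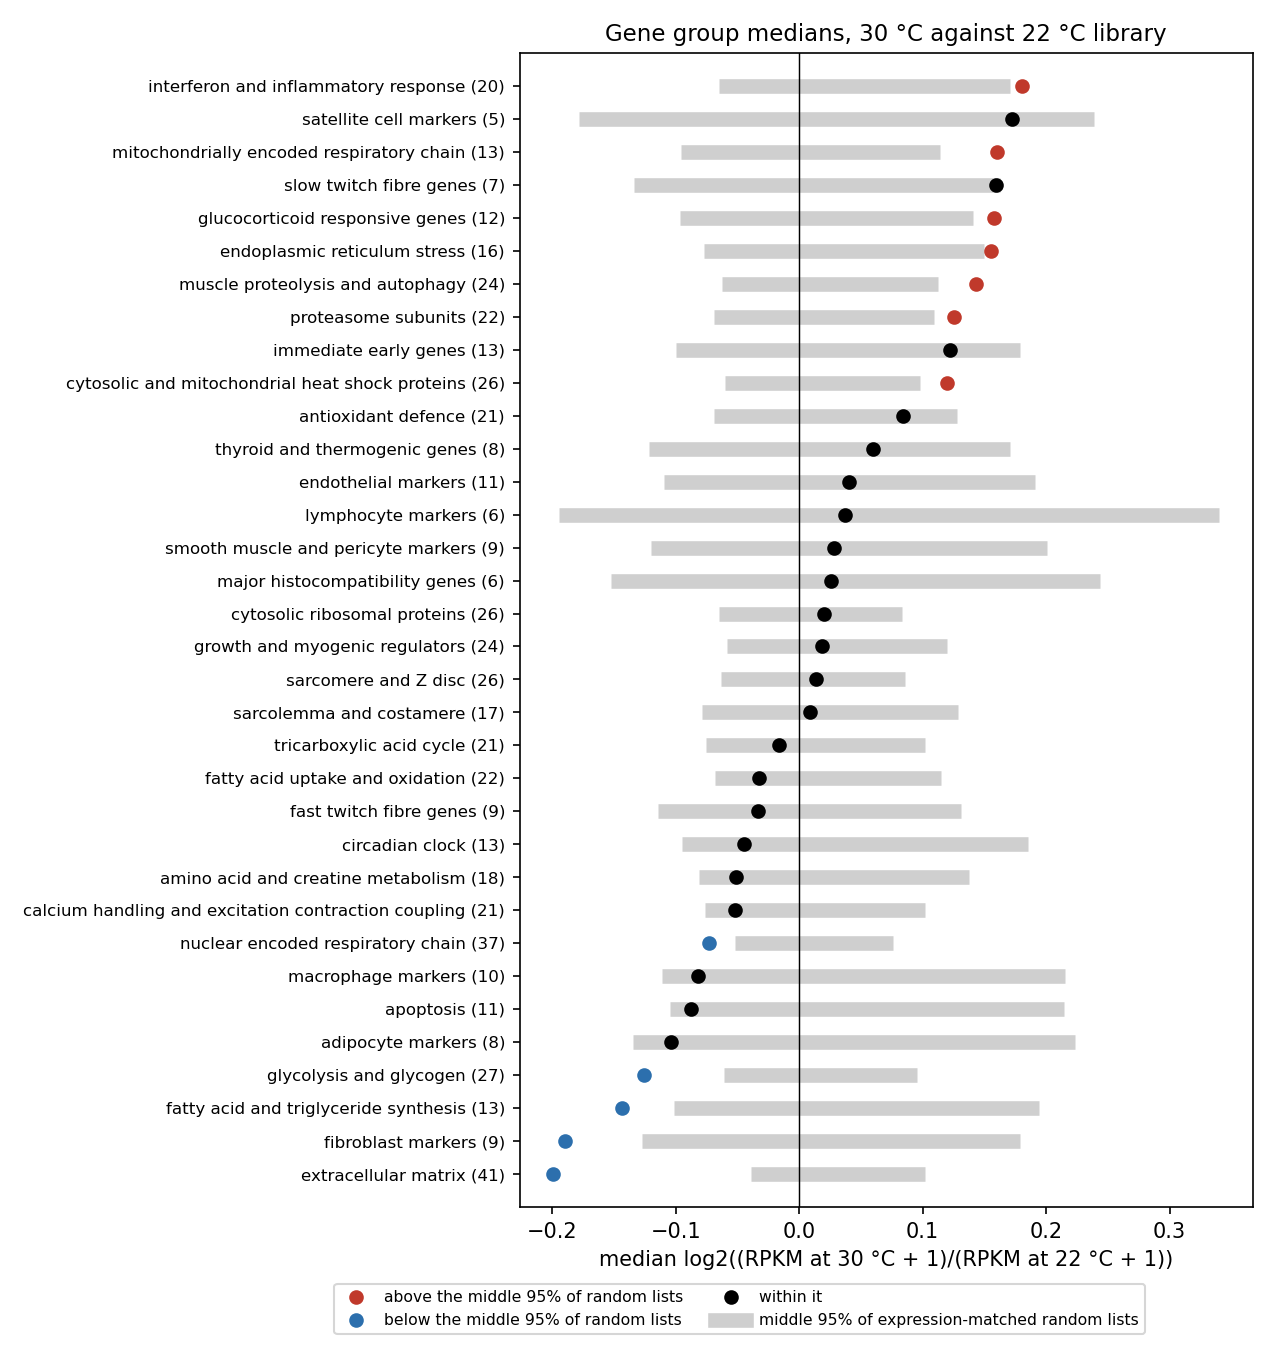
Median log2 ratio of the 30 °C to the 22 °C library (horizontal axis) of the 34 gene groups with at least 5 measured members, whose number is in brackets. Grey bars span the middle 95% of random lists matched on expression. The 7 red groups lie above their bar and the 5 blue groups, with extracellular matrix the lowest at -0.20, lie below it.

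Fibre type groups did not stand apart, but both were matched only in part. Of 16 listed members each, 7 slow and 9 fast genes were matched, without MYH1, MYH2, MYH4 or MYH7. MYLPF was missed too, since the gene names used here give it as MYL11 (log2 ratio -0.09). The counting interval lay above 1 for 5 slow members and below 1 for 2. The slow fibre group had a median of 0.16 over 7 genes (percentile 97.3), led by CSRP3, a Z disc protein that responds to stretch (102 to 188 RPKM, 0.87), and the slow myosin light chain MYL3 (591 to 802, 0.44), with MYH7B (-0.34) and LMCD1 (-0.40) lowest. It passed the upper limit with a pseudocount of 5 (97.97), by its mean (97.9) and when rescaled without the 10 highest genes (97.51). The fast fibre group had a median of -0.03 over 9 genes (percentile 26.5), with PVALB as its only member at least 1.5-fold apart. Sarcomere and Z disc genes (0.01), sarcolemma genes (0.01) and cytosolic ribosomal proteins (0.02) had medians near 0. Endothelial markers (0.04) and smooth muscle and pericyte markers (0.03) also lay within the random range. Of red blood cell markers only 2 were measured and of Schwann cell markers 3, too few for a percentile. HBB, a haemoglobin chain singled out after its values were seen, was at 89.0 and 112 RPKM.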

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

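Matching on recovered length, on expression and length together or on the 100 nearest genes, genes with a symbol only and the counting interval were chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 library. No group or named gene past its threshold turned direction in the alternatives run. The counts of 83 higher and 77 lower genes became 290 and 193 with a pseudocount of 0.1, 7 and 20 with 5, 17 and 26 with a mean RPKM of at least 5, 184 and 230 with a threshold per expression bin, and 10 and 10 with a symbol. No filter gave 121 and 104, and 57 and 54 had a counting interval that excluded 1, while 6 and 8 were at 0 in either library and have no interval. The counts were 68 and 86 when centred, 68 and 83 by the trimmed mean and 97 and 72 without the 10 highest genes. Scaling alternatives moved the median of all genes by less than 0.1. Of the 12 groups that stood apart, the matrix group did so in all 14 alternatives. Of these, the 3 rescalings shift all genes nearly alike and summing entries touched 1 symbol, so these 4 can hardly move a percentile. Without matching, percentiles inside the limits were heat shock 91.6, endoplasmic reticulum stress 95.1, glucocorticoid 92.5, mitochondrial genes 93.4, proteolysis 95.7 and proteasome 91.7. With length matching the same groups were at 91.1, 94.95, 93.3, 91.9, 96.1 and 91.1. With expression and length matched together, 11 of the 12 stood apart and the glucocorticoid group was at 97.47, so length alone, which leaves expression unmatched, gave nearly what no matching gave. Recovered lengths of genes with many reads can be far too short, which limits both length matches. By list means heat shock was at 96.15, endoplasmic reticulum stress 91.3, fibroblast 5.56, glycolysis 7.56, interferon 97.2, nuclear chain 5.62 and proteasome 95.6. A pseudocount of 5 gave glucocorticoid 96.2 and interferon 93.1, a mean RPKM of at least 5 gave fatty acid synthesis 4.54 and interferon 95.6, and no filter gave heat shock 96.45. Apart from fewer genes under the stricter filter, the cause was not tested. Depth limits small genes most, since 1 read on a gene of 100 bp is worth 0.424 RPKM.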

Other observations

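The 3 patterns weighed below were picked, and matching on length or on the nearest genes was added, after the list results were seen. The tests of fibroblast, adipocyte and muscle fibre content and of counting error in SCD and FASN were chosen only after the values they use were seen, while the list medians and the list mean were planned. Some single genes were the highest members of groups that did not stand apart. ATF3, a stress-induced transcription factor, was at 52.7 RPKM in the control library and 84.7 in the heat library (log2 ratio 0.67). CASP6, an executioner caspase, was at 1.84 and 3.73 (0.74), AMPD3, an AMP deaminase, at 1.02 and 3.01 (0.99), and FHL3, a LIM protein of muscle, at 16.2 and 25.9 (0.64). The fetal and cardiac actin ACTC1 came next to FHL3 in its group, at 16.8 and 25.4 RPKM (0.56). Among mitochondrial fuel genes, UCP3, a carrier of the inner membrane, was at 20.6 and 28.7 (0.45), and CPT1A, which admits fatty acids to mitochondria, was next at 8.44 and 11.4 (0.39). The lowest members of these groups included GADD45B, a stress-induced growth arrest gene (-0.42), the cell death gene BID (-0.46), ACAA1, a thiolase of peroxisomes (-0.39), GAMT, which makes creatine (-0.27), and ANKRD2, a stretch-responsive muscle protein (-0.28). The medians of fatty acid oxidation (-0.03), tricarboxylic acid cycle (-0.02), antioxidant (0.08), immediate early (0.12), circadian (-0.05), thyroid and thermogenic (0.06), amino acid and creatine (-0.05), calcium handling (-0.05), growth and myogenic (0.02), apoptosis (-0.09), histocompatibility (0.03) and satellite cell genes (0.17) lay within their random ranges. Calcium handling passed the lower limit when matched on length (2.47).

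Among the 141 genes with a mean RPKM of at least 500, 4 were at least 2-fold lower in the heat library and 0 higher. All 4 lack a symbol, and their summed RPKM was 27693 in the control library and 7583 in the heat library, or 3.87% and 1.08% of each library's sum. These are shares of RPKM, not of reads. With the minimum reads, the lengths of these genes came out at 23 to 153 bp, shorter than the fragments of about 200 bp. For genes with many reads such lengths can be far below the true ones, so whether these genes are short is unknown. A short length would raise RPKM. ENSSSCG00000025162 went from 13396 to 3547 RPKM (at least 7274 and 1865 reads) and ENSSSCG00000020149 from 2019 to 239 (at least 7291 and 835 reads). The largest log2 ratio in size among the other genes at this level was 0.44. On the other side, ENSSSCG00000008882 was at 1.97 and 85.9 RPKM (at least 30 and 1269 reads) and ENSSSCG00000024482 at 0.285 and 27.4 (6 and 559 reads). Of 24 small nucleolar RNAs with a mean RPKM of at least 1, 8 were at least 2-fold apart (33.3%), against 12 of 6966 other genes with a symbol (0.172%). Their median was 7 minimum reads in the control library, against 293.5 for the others, and the counting interval excluded 1 for 3 of the 8.

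The lower extracellular matrix genes could come from length, from counting error or from a tissue sample with fewer fibroblasts. Among random lists matched on recovered gene length the group's percentile was 0. This argues against length bias as the whole cause only as far as the recovered lengths hold. Counting error would put as many members on each side, and 29 had an interval below 1 with 2 above. Fewer fibroblasts stays open, since the 6 fibroblast markers outside the list had a median log2 ratio of -0.23 with quartiles of -0.30 and 0.04, while DCN, an abundant fibroblast gene of the matrix list singled out after its value was seen, was at 186 and 190 RPKM. Lower matrix expression at 30 °C is an untested hypothesis beside it, and the 2 cannot be told apart without cell counts or further libraries.

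A candidate explanation of the lower SCD and FASN is fewer adipocytes within the muscle sample, and lower expression of both genes at 30 °C is an untested hypothesis beside it. Counting error is excluded as the whole cause, as the higher upper bound of the 2 intervals of the RPKM ratio was 0.479. The 8 adipocyte markers had a median log2 ratio of -0.10 with quartiles of -0.27 and -0.01, and by their mean they stood apart on the low side (percentile 2.08). CIDEC (-0.93) and PLIN1 (-0.53) were low while CFD, singled out after its value was seen, at 123 and 119 RPKM and the most abundant marker, was not, and muscle fibres express some of these genes, such as PLIN4. Adipocyte content therefore stays open, and adipocyte counts or further libraries would be needed to decide.

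The lower glycolysis group could follow a trend with expression level, gene length or a smaller share of muscle fibre RNA. Among lists of the genes nearest in expression its percentile was 0.14, so a trend with expression level does not account for it. Among lists matched on recovered length the percentile was 0.05. Many of these genes have many reads, and their recovered lengths can be far too short, so this match cannot decide on length bias. The median of 26 sarcomere and Z disc genes lay 0.14 above that of the glycolysis group, within their interquartile range of 0.21, with 14 above 0 and 12 below. The sarcomere group itself was not low, with a median of 0.01 at percentile 50.6. That interquartile range is the spread of single genes and not of a median. The random range for medians of the sarcomere group was -0.06 to 0.09, and the glycolysis median of -0.13 lay below it. Less fibre RNA would lower sarcomere genes too, so these values argue against it as the whole cause, for the genes measured. Fast fibre (-0.03) and calcium handling genes (-0.05) had medians below 0 but within their random ranges, so a smaller contribution stays open. By the list mean, however, the glycolysis group was at percentile 7.56, and PFKFB3 (1.01) enters that mean. Lower glycolytic expression at 30 °C is an untested hypothesis beside these, which fibre counts or further libraries would be needed to decide.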
